A study of Mus musculus with 8 samples.

How the data were processed

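Colon epithelium of 8 male hCYP1A mice, which carry a humanized CYP1A locus on a C57BL/6 background, was profiled with 1 array per mouse. Per the labels' protocols, the mice ate AIN93M diet and received PhIP, a heterocyclic amine formed in cooked meat, once by gavage at 200 mg/kg, or PBS, at 8 weeks of age. After 24 hours the crypt epithelium was scraped from the colon under a dissection microscope. Groups came from the sample titles and held 3 PBS mice and 5 PhIP mice.

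Per the labels' protocols, total RNA was turned into biotin-labelled cRNA and read in 1 colour with Alexa-647 on spotted long-oligonucleotide arrays. Per the file headers, the arrays were scanned at 635 nm and read with GenePix Pro 4.1.1.4, with local background and no normalization. The deposited scanner value used here was the spot's median intensity minus its local background, on a linear scale that can fall below 0. The deposited scanner files also give each spot a quality score, the flag, which marks it as found, not found, empty or bad. The deposited series matrix held log2 values. Set against the scanner files, 7 of its columns equalled the log2 of a scan's background-subtracted intensity, with values under 1 raised to 1, plus 1 constant per array. The authors' log2 matrix is thus not centred per gene, and its column medians lay between 4.68 and 5.13. Whether those constants came from a normalization is not given in the sources used here.

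The scans and the matrix did not pair throughout. The matrix column of PhIP mouse 1 held the values of the scan deposited with PhIP mouse 2, and the column of PhIP mouse 2 matched none of the scans used here. The scan deposited with PhIP mouse 1 had no counterpart in the matrix. Each of these belongs to the PhIP group by its label, so the comparison of groups is affected only through which arrays enter it. That scan was taken at a photomultiplier gain of 700, against 650 for the others. It found 7501 probes above background, against 18861 to 20040 on the other arrays, and is called the dim array below. The fixed analysis used all 8 scans. Some results without the dim array, and with the authors' matrix turned back to intensities, are given beside it. Leaving that array out was planned because of its gain. A value given without stating otherwise is from 8 arrays and includes it. Giving the value without it beside many results, and the use of the authors' intensities, were chosen after the data were seen.

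Each array held 38880 spots, of which 35078 were mouse probes and 3802 were control or empty spots, which were left out. Intensities were quantile normalized between arrays on the linear scale and raised to a floor of 21.25, the percentile 5 of normalized values found above background. They were then put on the log2 scale, where the floor is 4.41. A fold against a group at the floor is therefore a lower bound. Probes were tested if the scanner software found them on at least 3 arrays, and 23 probes flagged bad were left out. Probes were named by matching their RefSeq accession to a gene table of assembly GRCm38.p6, which gave 1 symbol for 23071 probes and none for 12007. The probe with the highest mean stood for each gene. Among 3150 genes with several tested probes, 0 had probes with an unadjusted p under 0.05 in opposite directions. This left 15854 features, 10951 of them named.

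PhIP was compared with PBS by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), 2-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Of 50 gene lists written before the data were examined, 47 had at least 5 tested members. These were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 47 lists. Camera asks whether a list ranks apart from the other genes. An estimated correlation and fry were alternatives. Fold errors are limma standard errors (SE), and group values are means ± SD of normalized log2 intensity. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

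The steps were tested on simulated data drawn from the real means and residual spreads, with 200 genes changed per simulation and 20 simulations per comparison. With the spreads of all 8 arrays over 15854 features, 16.2% of 2-fold changes and 50.7% of 4-fold changes were recovered, and 7.49% of calls were unchanged genes, against a nominal 5%. With the spreads of the 7 other arrays over 15842 features, 53.9% and 86.0% were recovered, and 6.74% of calls were unchanged genes. A p53 target list shifted by 0.5 passed in 20 of 20 simulations of either kind. The simulated genes varied independently, so this does not test the preset correlation. Each gene had the same spread on every simulated array. The 8-array simulations therefore do not reproduce data in which 1 array stands apart.

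The rule for named genes was also fixed in advance. It took up to 12 genes per direction that passed with non-overlapping groups. Where fewer than 5 did, it filled each direction to 8 by the smallest unadjusted p. It added up to 4 members with the smallest p of each described list, and 11 genes in any case. A few genes that the rule picked are not reported here. The 18 lists described were picked after their values were seen. Alternatives covered normalization, background correction, floor, filter, probe choice, variance model, array weights, arrays marked as re-dipped, slide number range, mouse number and each mouse left out. All scans were taken on 1 day. The number of arrays limits the precision.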

Results

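The arrays measured the transcripts of scraped colon crypt epithelium 24 hours after 1 oral dose of PhIP (200 mg/kg, 5 mice) or PBS (3 mice). The stated purpose of the series was to find genes whose expression PhIP changes in the colon of mice with the humanized CYP1A genotype. On 7 of the 8 arrays, 53.8% to 57.1% of the mouse probes were found above background. On the array deposited with PhIP mouse 1, the dim array, 21.4% were found. Pairs of the other 7 arrays correlated at 0.97 or more over the tested features. The dim array had a median correlation of 0.77 with the rest. Its housekeeping control spots had a median signal of 4216, against 29200 to 39750 elsewhere.

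**Figure D1:**
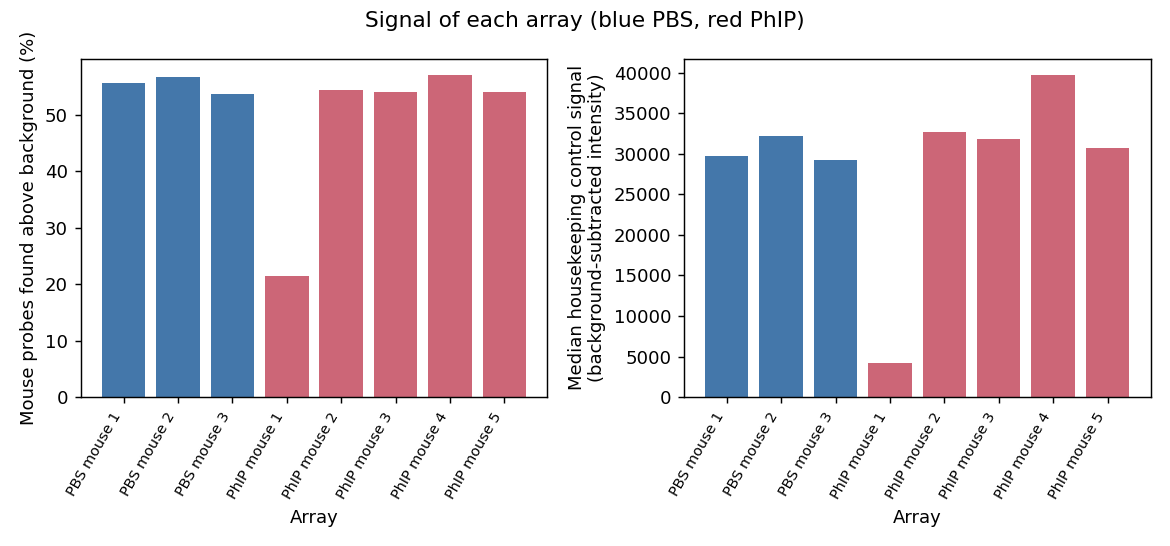
Share of mouse probes found above background (left, percent) and median background-subtracted intensity of the housekeeping control spots (right) on each of the 3 PBS arrays (blue bars) and 5 PhIP arrays (red bars). The array of PhIP mouse 1 lies at 21.4% and 4216, below all others.

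Transcripts of p53 target genes led the comparison. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 5.68-fold in PhIP mice, from a log2 intensity of 8.68 ± 0.30 (SD, n = 3) to 11.19 ± 0.17 (SD, n = 5). Its log2 fold change was 2.51 (SE 0.17, limma adjusted p = 0.00601). Eda2r, a receptor of the TNF receptor family and a p53 target, rose 4.70-fold, with a log2 fold change of 2.23 (SE 0.21, adjusted p = 0.0371). Both genes were higher on 5 of 5 PhIP arrays than on any PBS array. They were the only features of 15854 to pass with 8 arrays, so 2 rose and 0 fell. With the slide number range as a block the log2 fold changes were 2.60 (adjusted p = 0.063) and 2.56 (adjusted p = 0.0769), and with re-dipping as a block 2.56 (adjusted p = 0.0209) and 2.28 (adjusted p = 0.129), for Cdkn1a and Eda2r in turn. Against the 1 PBS array of the PhIP arrays' slide range they were 2.60 and 2.56. Within the re-dipped arrays they were 2.59 and 2.07, and within the others 2.52 and 2.56. The re-dipped arrays were 2 PBS arrays, the dim array and PhIP mouse 3. PBS mouse 3 was the only PBS array not re-dipped and the only one in the PhIP arrays' slide range, so fits within those arrays, and estimates with slide range as a block, rest on 1 PBS array. By unadjusted limma p under 0.05, 229 features were higher and 259 lower, 488 in all, where chance gives 793. The groups did not overlap for 911 features, or 5.75%, where chance gives 3.57%.

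The calls depended on the arrays used. With 7 arrays, leaving out the dim one, 5 genes rose and 0 fell by limma, and 1469 features had an unadjusted p under 0.05. The 5 genes were Cdkn1a, Eda2r, Ephx1, Aaas and Phlda3. Leaving out PBS mouse 2, PBS mouse 3, PhIP mouse 3 or PhIP mouse 5 left 0 genes, and leaving out PBS mouse 1, PhIP mouse 2 or PhIP mouse 4 left 1 that rose. Without PBS mouse 1, 1 gene also fell (Prol1). With the authors' arrays through the same steps, 7 genes rose (those 5 with Mdm2 and Polk) and 1 fell (Fhit). Phlda3 and Polk lay outside the naming rule and were named after their values were seen.

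**Figure D2:**
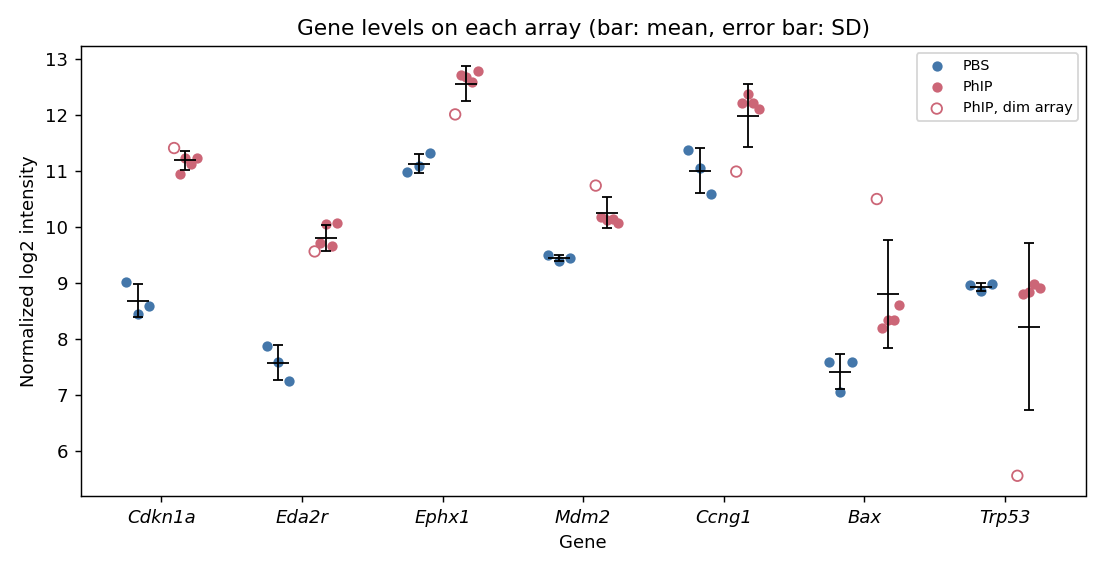
Normalized log2 intensity of 7 genes on each array, with PBS mice in blue and PhIP mice in red, the dim array as an open circle, and black bars for the mean and SD of 3 PBS and 5 PhIP arrays. Cdkn1a and Eda2r are higher on every PhIP array than on any PBS array, and for Trp53 the dim array lies at 5.56, against 8.81 to 8.98 on the other PhIP arrays.

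Of 39 measured p53 target genes, 29 had positive and 10 negative log2 fold changes, with a median of 0.50. The list ranked higher in PhIP by camera (adjusted p = 4.69e-08). That call was lost with an estimated correlation (adjusted p = 0.272) and kept with it once the dim array was left out (adjusted p = 0.00565), when 36 members were positive. The median was 0.40 with slide range as a block and within the shared range, and 0.18 within the re-dipped arrays (camera adjusted p = 0.222), where the PhIP arm is the dim array (list mean -0.04 against PBS) and PhIP mouse 3 (0.68). Over all genes 2 members rose, and adjusted over the list alone 7 did. With 7 arrays 20 rose adjusted over the list alone. Psrc1, which encodes a spindle protein, was at the floor in all PBS mice and had a log2 fold change of at least 1.35 (SE 0.20, adjusted p = 0.46). Mdm2, the ubiquitin ligase that degrades p53, had 0.80 (SE 0.18, adjusted p = 0.837), and 0.68 (SE 0.07, adjusted p = 0.0516) without the dim array. Ccng1 had 0.98 (SE 0.34) and the apoptosis effector Bax 1.38 (SE 0.53), and neither passed. With 7 arrays these were 1.22 (SE 0.17) and 0.95 (SE 0.18). Phlda3, a repressor of Akt signalling, had 1.10 (SE 0.28) with all arrays and 1.29 (SE 0.11, adjusted p = 0.0203) without the dim one. Polk, a translesion DNA polymerase, had 0.35 (SE 0.87) and 1.08 (SE 0.12). Trp53 itself had -0.72 (SE 0.78), and -0.05 (SE 0.09) without the dim array.

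Outside that list, Ephx1, which encodes microsomal epoxide hydrolase, had the largest value among the genes that did not pass on all 8 arrays but passed without the dim one. Its log2 fold change was 1.42 (SE 0.20, adjusted p = 0.309) with 8 arrays and 1.54 (SE 0.09, adjusted p = 0.00317) with 7. Aaas, a nuclear pore protein, had 1.00 (SE 0.16) and 1.06 (SE 0.10, adjusted p = 0.032). The other genes that filled the higher direction by smallest p did not pass in either. These were Map3k20, at the floor in all PBS mice, at 1.65 or more (SE 0.31, and 1.11 with 7 arrays), the thiamine transporter Slc19a2 at 0.95 (SE 0.19) and Fbxw9 at 0.74 (SE 0.15). In the lower direction no gene passed with 8 or 7 arrays. Fhit was not well above background on any PhIP array and was at least 2.51-fold lower there (log2 fold change -1.33, SE 0.16, adjusted p = 0.175). Prol1 was found on 3 of 3 PBS arrays and 1 of 5 PhIP arrays, with log2 intensities of 9.69 ± 2.18 (SD, n = 3) and 4.47 ± 0.15 (SD, n = 5). It lay at the floor on most PhIP arrays, so its log2 fold change of -5.21 (SE 0.82, adjusted p = 0.527) is in part a bound. It passed without PBS mouse 1 (-6.43, adjusted p = 0.00699). Retnla, Ldb3 and Pcsk2 had -1.16 (SE 0.23), -0.92 (SE 0.19) and -0.75 (SE 0.16). For Ldb3 and Pcsk2 some PhIP arrays lay at the floor, so their values are partly bounds.

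With 8 arrays no list of xenobiotic metabolism genes passed. The mouse Cyp1a1 and Cyp1a2 probes, for the mouse counterparts of the humanized locus, were not well above background on any array and were not tested. They do not show whether PhIP changed the human genes. Cyp1b1 had a log2 fold change of 0.01 (SE 0.33). Of 14 AhR battery genes, the targets of the aryl hydrocarbon receptor, 4 were positive and 10 negative, with a median of -0.22 (camera adjusted p = 0.0912) and -0.04 without the dim array. It ranked lower without PBS mouse 1 (-0.34, adjusted p = 0.0166), PhIP mouse 2 (-0.26, adjusted p = 0.0448) or PhIP mouse 3 (-0.27, adjusted p = 0.0451), and with no filter on dim probes (-0.06, adjusted p = 0.0276), all at the preset correlation. With an estimated correlation its adjusted p on 8 arrays was 0.717. Nqo1 had -0.89 (SE 0.56) and Ugt1a6b -0.95 (SE 0.47), and with 7 arrays -0.50 (SE 0.30) and -0.63 (SE 0.30). Of 26 Nrf2 target genes the median was 0.07 (camera adjusted p = 0.496), and of 18 settings they ranked higher only in the authors' matrix as deposited (0.14, adjusted p = 0.00507). With an estimated correlation their adjusted p was 0.759 with 8 arrays and 0.578 with the authors' arrays. Adjusted over the list alone 2 rose, which were Ephx1 and the glutathione transferase Gsta3 at 0.72 (SE 0.16). The 23 phase I and II enzymes had a median of 0.21 (camera adjusted p = 0.424) and 0.09 with 7 arrays, with Cyp2e1 at 1.02 (SE 0.26).

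Of 22 genes of the G2 and M phases, 16 were negative, with a median of -0.52. The list ranked lower (camera adjusted p = 0.00112), and the call was lost with an estimated correlation (adjusted p = 0.382). Within the re-dipped arrays, where the dim array is 1 of 2 PhIP arrays, the median was -0.04 (camera adjusted p = 0.836), and with 7 arrays it was -0.48. Ccnb1, the mitotic cyclin B1, had -0.96 (SE 0.19), Kif23 -0.92 (SE 0.35), Cenpe -0.50 (SE 0.22) and Ccna2 -1.06 (SE 0.50). None of these 4 passed over all genes, and Ccnb1's other probe had the opposite sign. Ccnb1's value is partly a bound, since some PhIP arrays lay at the floor. Kif23 and Ccna2 lay at the floor on the dim array, and with 7 arrays had -0.69 (SE 0.21) and -0.78 (SE 0.37). The proliferation marker Mki67 had no matched probe. The 23 S phase genes had a median of 0.02 (camera adjusted p = 0.727) and 0.14 with 7 arrays, with Chaf1b at 0.90 (SE 0.41). The 21 genes of the apoptosis machinery had -0.16 (camera adjusted p = 0.915) and -0.03 with 7 arrays, with Birc3 at 0.48 (SE 0.23). The 23 nucleotide excision repair genes had 0.16 and did not pass (camera adjusted p = 0.1). With 7 arrays they ranked higher, with a median of 0.17 (adjusted p = 0.0113, and adjusted p = 0.526 with an estimated correlation). Over all arrays Ercc5 had 0.79 (SE 0.38) and Pole 0.64 (SE 0.33), and with 7 arrays 0.48 (SE 0.12) and 0.51 (SE 0.29). Ercc5 stood at a log2 intensity of 11.18 on the dim array, against 9.565 to 9.693 on the other PhIP arrays. It is also a member of the p53 target list, so the repair list is not separate from that list.

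Cholesterol synthesis genes ranked lower. Of 18 members 15 were negative, with a median of -0.60 (camera adjusted p = 1.14e-06). The call was lost with an estimated correlation (adjusted p = 0.272). With 7 arrays 17 were negative, with a median of -0.31, and within the arrays not re-dipped, with their 1 PBS array, it was -0.23 (camera adjusted p = 0.123). Adjusted over the list alone 3 fell with 8 arrays and 6 with 7. Idi1 had -0.99 (SE 0.21), Cyp51 -0.84 (SE 0.18) and Fdps -0.70 (SE 0.29). The 19 genes of the unfolded protein response had a median of -0.64 (camera adjusted p = 0.00405, and adjusted p = 0.717 with an estimated correlation), and -0.26 without the dim array. That call ended without PBS mouse 2 (-0.55, adjusted p = 0.0552). In the fits that rest on the 1 PBS array it was also lost, within the arrays not re-dipped (-0.04, adjusted p = 0.71), with slide range as a block (-0.45, adjusted p = 0.402) and within the shared range (-0.45, adjusted p = 0.481). The chaperone Hsp90b1 had -0.64 (SE 0.25) and Dnajc3 -0.66 (SE 0.25), while Ddit3, which encodes CHOP, had 0.55 (SE 0.19).

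Fibroblast, smooth muscle, MHC class II and squamous epithelium lists also ranked lower, while those of several other cell types did not pass. Endothelial markers had a median of -0.05 (camera adjusted p = 0.494), enteric neuron and glia markers 0.01 (adjusted p = 0.877) and adipocyte markers 0.43 (adjusted p = 0.246), the last 0.14 with 7 arrays. Of 18 settings, endothelial markers ranked lower in 1, adipocyte markers higher in 2, and neuron and glia markers passed in 0. Of 22 fibroblast and matrix genes 21 were negative, with a median of -0.54 (camera adjusted p = 3.47e-08, and adjusted p = 0.382 with an estimated correlation). It was -0.46 without the dim array, -0.25 without PBS mouse 3, -0.92 with slide range as a block and -0.26 within the re-dipped arrays (camera adjusted p = 0.302). The collagens Col3a1, Col5a1, Col1a1 and Col6a2 had -1.34 (SE 0.30), -1.04 (SE 0.26), -1.72 (SE 0.56) and -0.99 (SE 0.34). The 18 smooth muscle genes had a median of -0.24 (camera adjusted p = 0.012, and adjusted p = 0.529 with an estimated correlation). Among other settings, the call ended without PBS mouse 3 (-0.12, adjusted p = 0.301) or PhIP mouse 5 (-0.18, adjusted p = 0.0895) and with re-dipping as a block (-0.24, adjusted p = 0.0519), and within the re-dipped arrays the median was 0.05. The actins Actc1 and Actg2 had -3.53 (SE 0.91) and -0.31 (SE 0.19). All 6 MHC class II genes were negative, with a median of -0.77 (camera adjusted p = 9.98e-06, and adjusted p = 0.382 with an estimated correlation). Within the re-dipped arrays it was -0.42 (camera adjusted p = 0.472). H2-Ab1 had -0.89 (SE 0.20) and the invariant chain Cd74 -1.12 (SE 0.27), and adjusted over the list alone these 2 fell. The 11 squamous epithelium genes had -0.57 (camera adjusted p = 0.0361, and adjusted p = 0.68 with an estimated correlation). Krt5 had -1.04 (SE 0.63, and -0.56 with 7 arrays) and Ivl -0.93 (SE 0.53, partly a bound). Here too, leaving out PBS mouse 3 (-0.34, adjusted p = 0.301) or PhIP mouse 2, 4 or 5 ended the call. So did re-dipping as a block (-0.72, adjusted p = 0.059), among other settings. Without the dim array the median was -0.29 and the call was kept (camera adjusted p = 0.0334, and adjusted p = 0.877 with an estimated correlation). The erythroid list had 4 measured genes, too few for a list test, and its genes were named after their values were seen. The haemoglobins Hba-a1 and Hbb-b2 had log2 fold changes of -4.67 (SE 1.79) and -3.81 (SE 0.99), the second partly a bound since most PhIP arrays lay at the floor. With 7 arrays these were -5.64 (SE 1.49) and -4.40 (SE 0.77), while with 8 Slc4a1 and Alas2 had 0.33 (SE 0.20) and 0.02 (SE 0.45). None passed over all genes. The mean of these 4 genes against PBS was -0.26 on PhIP mouse 1 and -0.58 on PhIP mouse 2. It was -2.77 to -3.50 on PhIP mouse 3, 4 and 5, so the fall was uneven within the group.

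Among epithelial lists, the 8 goblet cell genes had a median of -0.35 (camera adjusted p = 0.0361, and adjusted p = 0.529 with an estimated correlation). Settings that ended the call included leaving out the dim array, at -0.23 (adjusted p = 0.0958), re-dipping as a block (-0.38, adjusted p = 0.113), and leaving out PBS mouse 1, PhIP mouse 4 or PhIP mouse 5. Agr2 had -0.61 (SE 0.27). The 13 intestinal stem cell markers had -0.20 (camera adjusted p = 0.448), -0.03 with 7 arrays and -0.42 without PBS mouse 1, with Lgr5 at -0.66 (SE 0.25, partly a bound, with 3 of 5 PhIP arrays at the floor) and Rnf43 at 0.43 (SE 0.25). By count, 1 list ranked higher and 8 ranked lower by camera with 8 arrays, and 0 passed with an estimated correlation or by fry. Without the dim array 4 ranked higher and 7 lower, 8 of them shared with the former 9, and 1 passed with an estimated correlation. The 16 clock genes had a median of 0.60 with 8 arrays (camera adjusted p = 0.0706) and 0.53 with 7 (adjusted p = 0.00888, and adjusted p = 0.526 with an estimated correlation). Tef had 1.07 (SE 0.24), Nr1d1 0.70 (SE 0.20), Dbp 0.97 (SE 0.37) and Nfil3 -0.65 (SE 0.21). The 27 interferon-stimulated genes had 0.16 (camera adjusted p = 0.134) and 0.25 with 7 arrays (adjusted p = 0.00484, and adjusted p = 0.877 with an estimated correlation), with Oasl1 at 1.13 (SE 0.37) and Irf7 at 0.75 (SE 0.28).

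**Figure D3:**
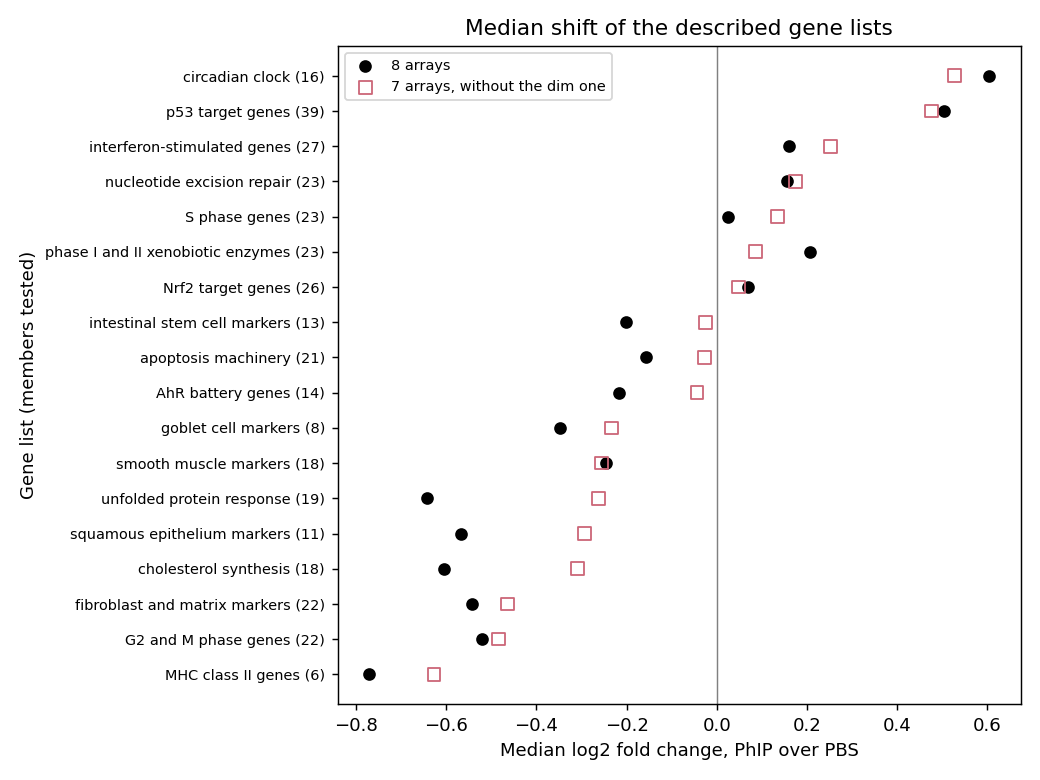
Median log2 fold change of PhIP over PBS for the 18 described gene lists, with the number of tested members after each name, from 8 arrays (black points) and from 7 arrays without the dim one (open squares). The p53 target list lies at 0.50 and 0.48, and the unfolded protein response list moves from -0.64 to -0.26.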

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

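The tests on the dim array's 2 treated-gene levels, and the second count of regroupings for the p53 list, were chosen only after the results were seen, and the other tests of the dim array and of regrouping were set out before. Within the 5 PhIP arrays, 30 of 103 values had 1 array far from the other 4, where chance gives about 1 in 20. Of these, 27 were on the array deposited with PhIP mouse 1. It found 21.38% of probes, had a housekeeping median of 4216, a background of 54 and a median correlation of 0.7661 with other arrays. Its list means against PBS stood apart for p53 targets (-0.03549), apoptosis (-1.031), cholesterol synthesis (-1.012), clock (-0.1195), the unfolded protein response (-2.073), AhR (-1.373), Nrf2 (-0.4854) and stem cell markers (-0.8389). Its log2 intensities stood apart for Bax (10.5), Ccng1 (10.99), Col1a1 (9.04), Ephx1 (12.01), Ercc5 (11.18), Fadd (10.29), Fdps (9.875), Mdm2 (10.74), Nqo1 (4.409), Pdia4 (7.618), Pold1 (9.212), Rgmb (4.409), Spdef (9.606), Trp53 (5.562) and Ugt1a6a (4.409). On other arrays, PhIP mouse 2 stood apart for Birc3 (10.48) and Prol1 (4.735), and PhIP mouse 3 for Col6a2 (8.796). For Prol1 the other 4 PhIP arrays lay at the floor of 4.409, so any value above it would have stood apart.

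Low signal of the whole hybridization is a candidate explanation of why the dim array stands apart. Its housekeeping spots reached 0.1444 of the lowest other array, as that explanation predicted. The same scan found few probes, so the dim spots describe its low signal and are no separate test. A control mouse labelled as treated is argued against by Cdkn1a and Eda2r, which also passed in the fit without this array. Its Cdkn1a log2 intensity was 11.41, where the highest PBS array had 9.02 and the other PhIP arrays 10.95 to 11.23. Its Eda2r level was 9.57, above the highest PBS array at 7.88. Other values went the other way. The array's p53 list mean against PBS was -0.04, where the other PhIP arrays had 0.63 to 0.68. Its Ccng1 level of 10.99 lay within the PBS range of 10.59 to 11.38. By contrast, its Bax (10.5) and Mdm2 (10.74) levels lay above the highest PBS arrays (7.60 and 9.50). They also lay above the other PhIP arrays (up to 8.61 and 10.18). Its Ephx1 level of 12.01 lay between the PBS arrays (up to 11.32) and the other PhIP arrays (12.58 or more). With so low a signal single levels are uncertain, so a wrong label is not excluded. Why the signal was low was not tested, and no biological explanation was tested for this array.

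At adjusted p under 0.05 the calls of single genes exceeded those of regrouped arrays. Of 56 splits of the 8 arrays into 3 and 5, only the real one, 1 split, gave 2 genes, and the highest other gave 1. Of 35 splits of the 7 arrays, only the real one, 1 split, gave 5 genes, and the highest other gave 1. These counts came in a share of splits under 0.05, so chance is unlikely for them, though not excluded. By unadjusted limma p under 0.05 the real split did not stand out. It gave 488 features with 8 arrays and 1469 with 7, where other splits gave up to 1501 and 1713. The splits do not separate treatment from slide range, in which PBS mouse 1 and 2 differ from the PhIP arrays. For the number of lists the share was not under 0.05. With 8 arrays 4 of 56 splits gave 9 lists or more, up to 13, and with 7 arrays 8 of 35 gave 11 or more, up to 16. For the p53 list alone, 3 of 56 splits of the 8 arrays gave a median as high as 0.5043, and the highest other was 0.5746. The 2 other splits set the dim array with 2 PBS arrays. Without it 1 of 35 splits, the real one, gave 0.4754, and the highest other was 0.2993.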

How the results depend on the processing

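Within-batch fits, the block of slide range for lists and the authors' arrays through the same steps were added after seeing the data. Cdkn1a was positive in all 27 settings (log2 fold change 2.29 to 2.67) and passed in 17, with adjusted p from 2.02e-05 to 0.72. Eda2r was positive in 27 (1.93 to 2.56) and passed in 8, with adjusted p from 0.000414 to 0.72. The main counts were 2 genes higher, 0 lower, 1 list higher and 8 lower. Leaving out each mouse gave 0 to 5 genes higher, 0 to 1 lower, 1 to 4 lists higher and 5 to 9 lower. The count of genes higher became 0 with the mouse number as a replicate block, with cyclic loess, with the mean of a gene's probes, with the slide range as a block, and within the re-dipped or the other arrays. It became 1 without a filter, with every probe tested, without a trend, with re-dipping as a block and within the shared slide range. It became 5 without the array of other gain, 7 with the authors' arrays, 10 with array weights, 13 with the authors' matrix as deposited, and 45 at unadjusted p under 0.05 with at least 2-fold. Genes lower became 1 with median scaling, no filter, array weights or the authors' arrays, 2 with the slide range block, 7 with the matrix, 9 within the shared slide range (against 1 PBS array) and 77 at unadjusted p. Lists higher became 2 with median scaling, no filter or within the shared slide range, 4 with the authors' arrays and 6 with the matrix. They became 0 within the re-dipped arrays. Lists lower became 5 with re-dipping as a block and 2 within the re-dipped arrays. Both counts of lists became 0 with an estimated correlation and with fry. The cause was not tested, except that block and within-batch fits hold fewer degrees of freedom or arrays.

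No clear pairing by mouse number was seen, but the values cannot exclude one. PhIP mouse 1 is the dim array, and the scans of PhIP mouse 1 and 2 did not match their matrix columns. Same-numbered mice deviated with correlations of -0.09, 0.19 and -0.12, and of the 3 only number 2 correlated best with its own number. The replicate block gave 0 genes higher and 0 lower.

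Some values changed sign, among which only the smooth muscle list had passed with 8 arrays. Cyp1b1 was -0.23 with median scaling, -0.0225 with cyclic loess, -0.0799 with re-dipping as a block, -0.403 with the slide range as a block and within it, -0.339 within arrays not re-dipped, and -0.177 to 0.212 without each mouse. S phase genes were -0.21 with the replicate block, -0.23 with median scaling, -0.0338 with the matrix, -0.111 with the slide range block and within it, -0.0477 and -0.0195 within re-dipped and other arrays, and -0.147 to 0.14 without each mouse. Median scaling gave -0.00696 for nucleotide excision repair, -0.0428 for Nrf2 targets and -0.0241 for interferon-stimulated genes. Apoptosis was 0.0812 with the matrix, 0.0281 with the authors' arrays and 0.18 within arrays not re-dipped. AhR genes were 0.0342 with the authors' arrays, and stem cell markers 0.0336 without a filter. Within the re-dipped arrays Actg2 was 0.00552, smooth muscle 0.0478 and Nrf2 targets -0.184. Within the others Fen1 was -0.113, Ifi44 -0.141, Pole -0.207 and Spdef 0.0151. Nrf2 targets lay between -0.0157 and 0.0858, and interferon-stimulated genes between -0.00433 and 0.25, without each mouse. Low signal over background on the dim array limits what 8 arrays can show.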

Other observations

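The test of the dim array as an explanation, and the comparison of fibroblast with endothelial and neural markers, were chosen after the list results were seen, and the tests of slide range and time of day were set out before. Several further lists did not pass with 8 arrays. The 31 cytosolic ribosomal protein genes had a median log2 fold change of 0.04 (camera adjusted p = 0.541), the 28 proteasome genes -0.01, the 26 oxidative phosphorylation genes -0.14 and the 14 Wnt target genes 0.01. Markers of T cells (9 genes, -0.11, adjusted p = 0.496), macrophages and dendritic cells (16 genes, -0.24, adjusted p = 0.448) and enteroendocrine cells (8 genes, -0.05) did not pass either. Of 18 settings, macrophage and dendritic cell markers ranked lower in 3, ribosomal protein genes higher in 2 and proteasome genes higher in 1.

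Fibroblast and smooth muscle markers were lower in PhIP by camera at its preset correlation, and neither passed with an estimated correlation (adjusted p = 0.382 and 0.529). Without PBS mouse 3 the fibroblast median was -0.25 and the smooth muscle call ended (-0.12, adjusted p = 0.301), and within the re-dipped arrays neither passed (-0.26, adjusted p = 0.302, and 0.05, adjusted p = 0.904). The dim array as the whole cause is argued against, since the fibroblast median was -0.4637 without it. Less stroma collected with the epithelium may be the source and stays open. Over the 7 arrays, 22 fibroblast genes differed by -0.52 (exact permutation p = 0.0286, the smallest 35 splits can give), and 27 endothelial and neural genes by -0.02 (exact permutation p = 0.886), but the difference between these shifts had an exact permutation p of 0.05714. The -0.02 pools lists that moved apart. Over all their tested members with 7 arrays, the endothelial median was -0.05 and the enteric neuron and glia median 0.12. Slide range also stays open. Against the PBS array of the PhIP arrays' range the fibroblast median was -0.9159, in the direction set out in advance as speaking against slide range, but that rests on 1 PBS array, PBS mouse 3, whose fibroblast mean (0.46) stood above those of the other PBS arrays (-0.22 and -0.23). An effect of PhIP on stromal transcripts stays untested.

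Clock genes ranked higher in PhIP by camera in the 7-array fit (median 0.53, adjusted p = 0.00888) but not with an estimated correlation (adjusted p = 0.526). With 8 arrays they did not pass (camera adjusted p = 0.0706). In both fits 5 of 16 were negative. At the preset correlation the list also passed without PBS mouse 3 (0.75), with no filter (0.58), with the authors' arrays (0.64, and adjusted p = 0.392 with an estimated correlation) and with their matrix (0.63), while with slide range as a block, which rests on 1 PBS array, the median was 0.02. A difference in time of day between the groups is a possible explanation. It predicts that genes peaking with Dbp and genes peaking with Arntl part. Over the 7 arrays 9 genes of the Dbp arm shifted by 0.76 and 4 of the Arntl arm by -0.57, with an exact permutation p of 0.05714 for the difference. With 8 arrays that p was 0.0357, so time of day cannot be told apart from an effect of PhIP with these arrays.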
